A study of Drosophila melanogaster with 2 samples.

How the data were processed

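Two-colour arrays were hybridised with RNA of control larvae and of larvae carrying the B52 transgene, in a dye swap of 2 arrays. Per the labels, channel 1 held the control RNA and channel 2 the B52 RNA on both arrays. Per the labels, control RNA carried Cy3 and B52 RNA Cy5 on replicate 1, and the dyes were exchanged on replicate 2. The molecule is labelled as cytoplasmic RNA for the control of replicate 1 and as polyA RNA for the other 3 channels. The labels do not say whether the arrays carried separate RNA extracts, so p-values measure only the spread between the arrays, which may be technical.

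The authors deposited 1 log ratio per spot and array, without intensities or flags in the table used here. The image analysis, background correction and normalisation are not given in the sources used here. The deposited medians over all spots were -0.006 on replicate 1 and 0.01 on replicate 2, near 0. Whether a centring step was applied is not stated. Neither the log base nor the direction of the deposited ratio is stated. The tests had been planned for log2 values, with the rule of 2-fold size at a log ratio of 1. As limma's test does not depend on the log base, it was run on the values as deposited. After the values had been seen, the size rule was set at 0.301 for log10 values in place of the planned 1, because of distances between control spots that do not settle the base, and the counts at 1 are given beside it. Dimness of a spot could not be judged without intensities, and random lists were not matched on it.

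Each array had 15744 spots. Blank spots numbered 1820 on replicate 1 and 1718 on replicate 2, and 5 spots of replicate 1 held the code -10000, treated as missing. The standard deviation of the tested probes was 0.191 on replicate 1 and 0.2 on replicate 2. The layout repeated in 24 sub-grids, and 40 unnamed positions were the same in each. Their 960 spots were taken as control spots and left out of all tests. Gene symbols came from the platform annotation: 13147 probes had 1 symbol, 99 had several and 2498 had none. Of probes with 1 symbol, 12519 matched a table of RefSeq gene symbols and 628 kept the symbol of the annotation. Probes with several symbols or none were tested but not named. The annotation may be old, and no genome build was named, so gene positions are not used here. Of probes with 1 symbol, 14.8% lacked a value on an array, among them 7 of 29 muscle probes and 5 of 16 phototransduction probes.

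B52 over control was read from the log ratios in 2 ways. The channel reading takes channel 2 over channel 1 with no sign turned. The dye reading takes Cy5 over Cy3 on both arrays and turns the sign of replicate 2. Each of the 12500 probes measured on both arrays was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 residual degree of freedom, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Tables, lists and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A ± value is the SD of the 2 arrays. For a list or family it is the SD of the 2 array medians. The median printed before it is taken over the gene means of both arrays, so it can lie outside the array medians. The intervals of the correlation and of the ratio of spreads came from resampling 48 print blocks. The test was tried on simulated data in 20 draws of 12500 probes with known changes, where the share of false calls was 8.58% in the channel reading and 11.3% in the dye reading, above the nominal 5%.

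Genes were grouped in 25 lists with 724 names, of which 696 matched a gene. Probes of 1 gene were averaged before a list median was taken. Each median was placed among the medians of 10000 random lists of the same number of named genes. Named genes followed a fixed rule. B52 was always named. Then came the 10 positive and 10 negative genes in the channel reading, and the 5 and 5 in the dye reading, with the largest smaller value of the 2 arrays among probes of 1 gene with the same sign on both arrays. In each list up to 3 genes could be named by the same value. The value printed for a named gene is that of 1 probe unless a mean over its probes is stated. The limma test, the size rule at a log ratio of 1, the list medians, the channel reading as the main one, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives covered the direction, centring and scaling of the arrays, averaging of probes, extreme values, the variance model, the threshold, the size and single arrays. Removal of print-block medians, restriction to named probes, inclusion of control spots, the size rule at 0.301 with its alternatives and all alternatives in the dye reading were added after the data were seen.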

Results

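RNA from larvae of the fruit fly Drosophila melanogaster was compared on 2 two-colour microarrays, each holding RNA of control larvae and RNA of larvae that carried the B52 transgene. B52 is an SR protein, a member of the serine- and arginine-rich family of splicing factors, and the transgene makes it as a fusion with green fluorescent protein. The control larvae carried green fluorescent protein with a nuclear localisation signal. Both crosses used GMR, in fly genetics the name of a promoter that is active in the developing eye. The question addressed was whether a raised level of B52 alters the expression of other genes. The dyes were swapped between the arrays: the B52 RNA carried Cy5 on replicate 1 and Cy3 on replicate 2. Replicate 1 had 13919 spots with a value and replicate 2 had 14026, and the 12500 probes measured on both arrays covered 10584 genes. The number of arrays limits the precision of every value below.

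The deposited log ratios state neither their direction nor their log base, so list medians, probe counts and the mean of the B52 probes are given in 2 readings. Most other values of single genes are given only in the reading named. In the channel reading the values of both arrays are B52 over control. For the dye reading they are Cy5 over Cy3, and the sign of replicate 2 is turned to give B52 over control. A positive value is higher in the B52 larvae in the reading named. Fold values are given for log10 and for log2 values side by side.

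No gene passed the test in either reading. In the dye reading, 7 lists had higher log ratios in the B52 larvae than random sets of genes. They were genes of muscle, cuticle, salivary gland, phototransduction, hemocytes, fat body and the hnRNP family of RNA-binding proteins. Cuticle was not higher in this reading with the 1% most extreme probes left out. In that reading, genes of the spliceosome core, the cell cycle and eye specification had lower ones. Of these lists only muscle, cuticle and phototransduction lay above the range of random lists on each array, and 0 lay below it on each array. In the channel reading, muscle and midgut lay below the range of random lists, and JNK signalling and wounding above it. Of these, 0 did so on each array. The JNK median was inside the range with print-block medians removed, and the muscle median lay above it on replicate 1 alone. No probe of B52 itself passed the test, and the mean of its 5 probes was below 0 in both readings. Single probes differed in sign, and in the channel reading the mean was above 0 on replicate 2 alone. The arrays thus did not show a raised level of B52 RNA.

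B52 was measured by 5 probes, all with a value on both arrays. The mean of the 5 probes was -0.0468 ± 0.126 (SD, n = 2 arrays) in the channel reading, a 1.11-fold difference if the values are log10 and 1.03-fold if they are log2. It was -0.0892 ± 0.0662 (SD, n = 2 arrays) in the dye reading, or 1.23-fold and 1.06-fold. The B52 probe with the largest value, probe 13309, had a deposited log ratio of -0.22 on replicate 1 and 0.60 on replicate 2. Its mean was 0.19 in the channel reading (limma adjusted p = 0.946) and -0.41 in the dye reading (limma adjusted p = 0.582). Of the other B52 probes, the lowest mean in the channel reading was -0.20 ± 0.14 (SD, n = 2 arrays; limma adjusted p = 0.801). The same probe had a mean of 0.10 ± 0.29 in the dye reading. The remaining B52 probes had dye-reading means of -0.0715, 0.0265 and -0.0935. The files do not tell which part of the B52 transcript each probe covers, so these values do not measure the transgene apart from the gene itself.

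Over all 12500 probes, limma called 0 at an adjusted p of 0.05 in the channel reading, where 815 probes had an unadjusted p under 0.05 and the lowest adjusted p was 0.705. Limma again called 0 in the dye reading, with 750 probes under an unadjusted p of 0.05 and a lowest adjusted p of 0.205. The robust form of limma and an ordinary 1-sample test also called 0 in both readings. Their counts at an unadjusted p under 0.05 were 807 and 725 in the channel reading, and 732 and 600 in the dye reading. Data were also simulated with independent noise from limma's variance model and 100 changed probes of each size. There limma recovered 85% of probes given a log ratio of 1 in the channel reading and 96.8% in the dye reading. Of probes given a log ratio of 0.301, it recovered 0.2% and 1.45%, so differences of that size were rarely detectable by this test with 2 arrays. The simulation held no print-block offsets and no dye effect, so recovery on the arrays themselves may differ.

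A rule of size was applied beside the test, without a p-value: the same sign and at least 2-fold on each array. It had been planned at a log ratio of 1, which is 2-fold if the values are log2, and 0 probes passed in either reading. After the values had been seen it was set at 0.301, which is 2-fold if they are log10. That cut was passed by 190 probes in the channel reading, 92 of them higher and 98 lower in the B52 larvae. Over probes with 1 gene symbol the split was 85 higher and 52 lower, and with print-block medians removed it was 54 higher and 78 lower over all probes. It was passed by 203 probes in the dye reading, 176 of them higher and 27 lower. There the split was 153 higher and 25 lower over probes with 1 gene symbol. With print-block medians removed it was 190 higher and 35 lower over all probes. Independent arrays with the same numbers of large values would give 36.8 higher and 20 lower probes in the channel reading, and 41.5 and 17.7 in the dye reading. These numbers assume that the size of a probe's value on replicate 1 is unrelated to its size on replicate 2. The counts over all probes exceeded them in both readings, which cannot both hold. The excess is therefore not a measure of shared change. Replicate 1 alone had 1123 probes past this size and replicate 2 alone had 1292.

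The probes with the largest values on both arrays in the channel reading came from genes of varied function. The 10 positive genes were sowi, Ugt35A1, CG15177, SNF4Agamma, Eip93F, lectin-21Ca, CtBP, CG1314, CG4956 and CG14930. Eip93F, an ecdysone-induced transcription factor, had a mean of 0.62 ± 0.16 (SD, n = 2 arrays), and SNF4Agamma, the gamma subunit of AMP-activated protein kinase, 0.60 ± 0.06. CtBP, a transcriptional corepressor, had 0.52 ± 0.03. The 10 negative genes were Cp7Fc, CG9777, CG32814, regucalcin, BNIP3, Gr61a, UQCR-11L, dnc, Rab3-GAP and CG14248. The chorion protein gene Cp7Fc had a mean of -1.19 ± 0.78, and dnc, a cyclic AMP phosphodiesterase, -0.49 ± 0.02. All 20 had a limma adjusted p of 0.705.

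The 5 positive genes of the dye reading were CG32241, Prx6b, CG12896, Cpr67Fa1 and Dnah3. Prx6b, a peroxiredoxin, had a mean of 0.80 ± 0.04 (SD, n = 2 arrays), which is 6.34-fold if log10 and 1.74-fold if log2, with a limma adjusted p of 0.205. Cpr67Fa1, a cuticle protein, had 0.77 ± 0.06 and the same adjusted p in limma. CG32241 had the highest mean of these, 1.27 ± 0.64, with a limma adjusted p of 0.289. The 5 negative genes were CG3528, Drs, CG17684, CG15818 and CG6602. Drs, which encodes the antifungal peptide drosomycin, had a mean of -0.60 ± 0.05 and a limma adjusted p of 0.294.

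**Figure D1:**
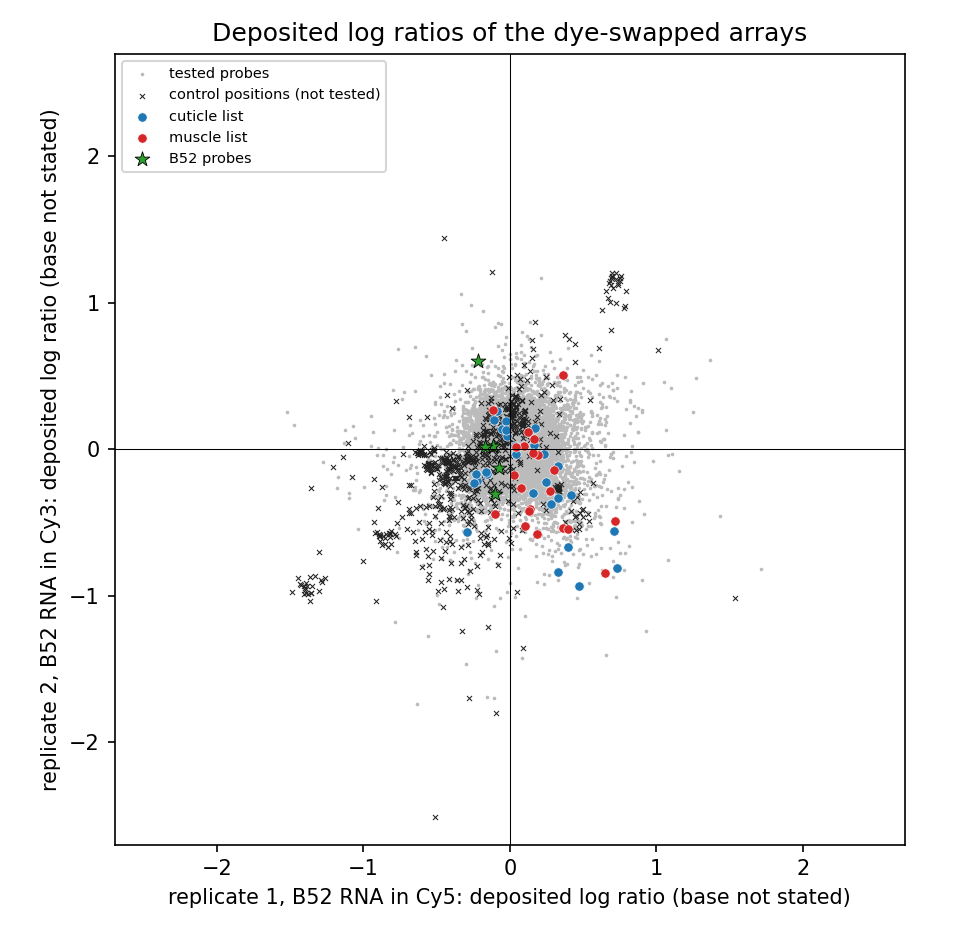
Deposited log ratio of each spot on replicate 1 (horizontal axis) against replicate 2 (vertical axis), log base not stated, with the tested probes in grey, control positions as crosses, and the cuticle list, muscle list and B52 probes in colour. The 176 tested probes at or above 0.301 on replicate 1 and at or below -0.301 on replicate 2 lie at the lower right, where many muscle and cuticle probes lie.

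The muscle list held structural genes of the sarcomere, and 18 of its genes were measured. Its median was 0.275 ± 0.179 (SD, n = 2 arrays) in the dye reading, 1.88-fold if log10 and 1.21-fold if log2, at percentile 100 among 10000 random lists. The value was positive on both arrays for 14 of the 18 genes and negative on both for 1. Examples were up, which encodes troponin T, at 0.75 ± 0.14, the tropomyosin gene Tm2 at 0.60 ± 0.16 and the myofilin gene Mf at 0.47 ± 0.10. Of the muscle probes, 5 passed an adjusted p of 0.05 in limma when adjusted over the list alone and 0 when adjusted over all probes. The muscle median in the channel reading was -0.0808 ± 0.408, with deposited medians of 0.162 on replicate 1 and -0.415 on replicate 2, and 0 probes passed when adjusted over the list alone. With both arrays scaled to the same spread it was -0.0492. Of the 18 genes, TpnC4 at -0.27 ± 0.24 was negative on both arrays in that reading, and Act88F at 0.12 ± 0.0049 and zormin, with a mean over its probes of 0.21, were positive on both.

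The cuticle list had 28 measured genes and a median of 0.0513 ± 0.0488 (SD, n = 2 arrays; percentile 99.48) in the dye reading. Of these, 13 were positive on both arrays and 6 negative on both. The medians on the single arrays were 0.0995 and 0.1685 (percentiles 99.8 and 100). With the 1% most extreme probes left out the median was 0.007 (percentile 74.47), inside the range of random lists. That step drops probes by the size of their own values, so it can remove the highest members of a list. With limma, 8 cuticle probes passed when adjusted over the list alone and 0 over all probes. Lcp65Aa had a mean of 0.63 ± 0.11 and Lcp9 of 0.70 ± 0.33, and both encode larval cuticle proteins. The salivary gland list had a median of 0.126 ± 0.0997 (percentile 99.95), with 9 of 15 genes positive on both arrays and 2 negative on both. On replicate 1 alone it was 0.054 (percentile 87.77), inside the range of random lists. Of its probes, 3 passed in limma when adjusted over the list alone, 0 over all. The glue protein gene Sgs1 had a mean of 0.51 ± 0.02 and the new glue gene ng1 0.48 ± 0.30. The channel reading gave a cuticle median of 0.0082, where the mean over the genes was -0.0428, and a salivary gland median of -0.0225, both medians inside the range of random lists.

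Genes of RNA processing also differed between the readings. The hnRNP list, RNA-binding proteins that package transcripts, had a median of 0.134 ± 0.0785 (SD, n = 2 arrays; percentile 99.97) in the dye reading and 0.0217 in the channel reading. On replicate 2 alone the dye-reading median was 0.0615 (percentile 90.42), inside the range of random lists, and over the arrays 6 of 10 genes were positive on both and 3 negative on both. A probe of Hrb27C had a mean of 0.38 ± 0.07, Psi 0.29 ± 0.03 and sm 0.27 ± 0.02 in the dye reading. The spliceosome core list had a median of -0.0715 ± 0.023 (percentile 0.31) in the dye reading, with 15 of 22 genes negative on both arrays and 1 positive on both, and -0.0072 in the channel reading. On replicate 2 alone it was inside the range of random lists (percentile 12.87). Prp8, a core protein of the spliceosome, had a mean of -0.17 ± 0.04, Sf3b1 had -0.12 ± 0.02 and Cdc5 had 0.13 ± 0.0042. The SR protein list, which includes B52, had medians of -0.081 in the dye reading (percentile 3.795) and 0.027 in the channel reading. The list of SR protein kinases and transportin had medians of 0.11 and 0.0634. In these 4 lists 0 probes passed in limma when adjusted over the list alone in either reading, as over all probes.

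Genes of the eye, where GMR is active, were in 3 lists. The phototransduction list had a median of 0.123 ± 0.0707 (SD, n = 2 arrays; percentile 99.89) in the dye reading, with 6 of 11 genes positive on both arrays and 2 negative on both, and 3 probes passed in limma when adjusted over the list alone, 0 over all. Examples were ninaB at 0.48 ± 0.08, Gbeta76C at 0.46 ± 0.19 and Arr2, an arrestin of photoreceptors, at 0.43 ± 0.29. The list of eye specification and photoreceptor development had a median of -0.0603 ± 0.0378 (percentile 0.54; 6.015 on replicate 1 alone), with 16 of 30 genes negative on both arrays and 3 positive on both. The gene ey was at -0.28 ± 0.19, aop at -0.21 ± 0.07 and Egfr at 0.18 ± 0.07. The eye pigment list had a median of 0.032 (percentile 90.03) and 2 probes passed in limma when adjusted over the list alone. The channel-reading medians of these 3 lists were 0.0555, 0.0408 and 0.0215, all inside the range of random lists. For eye pigment the channel-reading medians on the single arrays were negative, -0.036 and -0.06. The channel-reading phototransduction median lay above that range at 0.0902 (percentile 97.99) with both arrays scaled to the same spread and at 0.0815 (percentile 99.18) with print-block medians removed.

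Among the other lists in the dye reading, hemocytes had a median of 0.0575 (percentile 98.64) and fat body 0.0545 (percentile 97.53). On replicate 2 alone they were 0.009 (percentile 69.09) and 0.016 (percentile 73.06), and hemocytes were inside the range of random lists on replicate 1 too (percentile 91.8). The prophenoloxidase genes PPO2 and PPO1 of the hemocyte list had means of 0.48 ± 0.05 and 0.41 ± 0.24 (SD, n = 2 arrays). The cell cycle list had a median of -0.074 (percentile 0.435; 11.02 and 11.1 on the single arrays), and 11 of 19 genes were negative on both arrays and 2 positive on both. E2f1 was at -0.27 ± 0.11, Cdk2 at -0.17 ± 0.07 and 1 probe of CycE at 0.20 ± 0.0049. The remaining dye-reading medians were inside the range of random lists: 0.048 for JNK signalling and wounding, 0.0455 for antimicrobial peptides, 0.0395 for the nervous system, 0.03 for oxidative and xenobiotic stress and 0.0065 for heat shock. They were 0.0057 for sex-biased genes, -0.0035 for oxidative phosphorylation and -0.0157 for midgut digestive enzymes. They were -0.0225 for the ecdysone response, -0.0288 for housekeeping genes, -0.045 for ribosomal proteins and -0.0525 for apoptosis. With print-block medians removed, antimicrobial peptides (0.0575, percentile 97.61) and oxidative and xenobiotic stress (0.0512, percentile 97.95) lay above the range. Adjusted over the list alone, limma passed 2 probes of the antimicrobial list and 1 each of the midgut and hemocyte lists, with 0 over all probes.

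Of the 25 lists, 1.25 would on average lie outside the central 95% of random lists if each were a random set of named genes. Outside it lay 10 lists in the dye reading. In the channel reading 3 lists lay outside it. Besides muscle, these were JNK signalling and wounding, with a median of 0.0935 ± 0.099 (SD, n = 2 arrays; percentile 98.78), and midgut digestive enzymes, with -0.0705 ± 0.0117 (percentile 0.03). The JNK list included upd1, a ligand of the JAK/STAT pathway, at 0.39 ± 0.07, and its median on replicate 2 alone was -0.021. With print-block medians removed the JNK median was 0.037 (percentile 88.69), inside the range of random lists. The midgut medians on the single arrays were closer to 0, -0.042 and -0.0255, and inside the range (percentiles 8.415 and 12.87). In the midgut list 8 of 30 genes were negative on both arrays and 3 positive on both. The protease genes named from it were Jon99Fii at -0.30 ± 0.25, Jon99Ci at 0.21 ± 0.13 and zetaTry at 0.14 ± 0.0078. Replicate 1 alone put 9 lists outside the range and replicate 2 alone put 5. Genes of a list may vary together, which random lists leave out, so these counts are not a test. The other 22 medians were inside the range of random lists. They included -0.04 for oxidative phosphorylation, 0.0335 for fat body, 0.033 each for the cell cycle, the nervous system and the ecdysone response, 0.025 for sex-biased genes, 0.0187 for apoptosis and 0.0185 for heat shock. They also included 0.0165 for antimicrobial peptides, 0.0155 for oxidative and xenobiotic stress, 0.012 for ribosomal proteins, 0.002 for hemocytes and -0.0023 for housekeeping genes. The mean over genes had the opposite sign to the median for 6 lists in the channel reading (spliceosome core, eye pigment, ribosomal proteins, cuticle, antimicrobial peptides and housekeeping genes) and for 4 in the dye reading (oxidative phosphorylation, midgut, nervous system and housekeeping genes), all with medians inside the range of random lists.

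**Figure D2:**
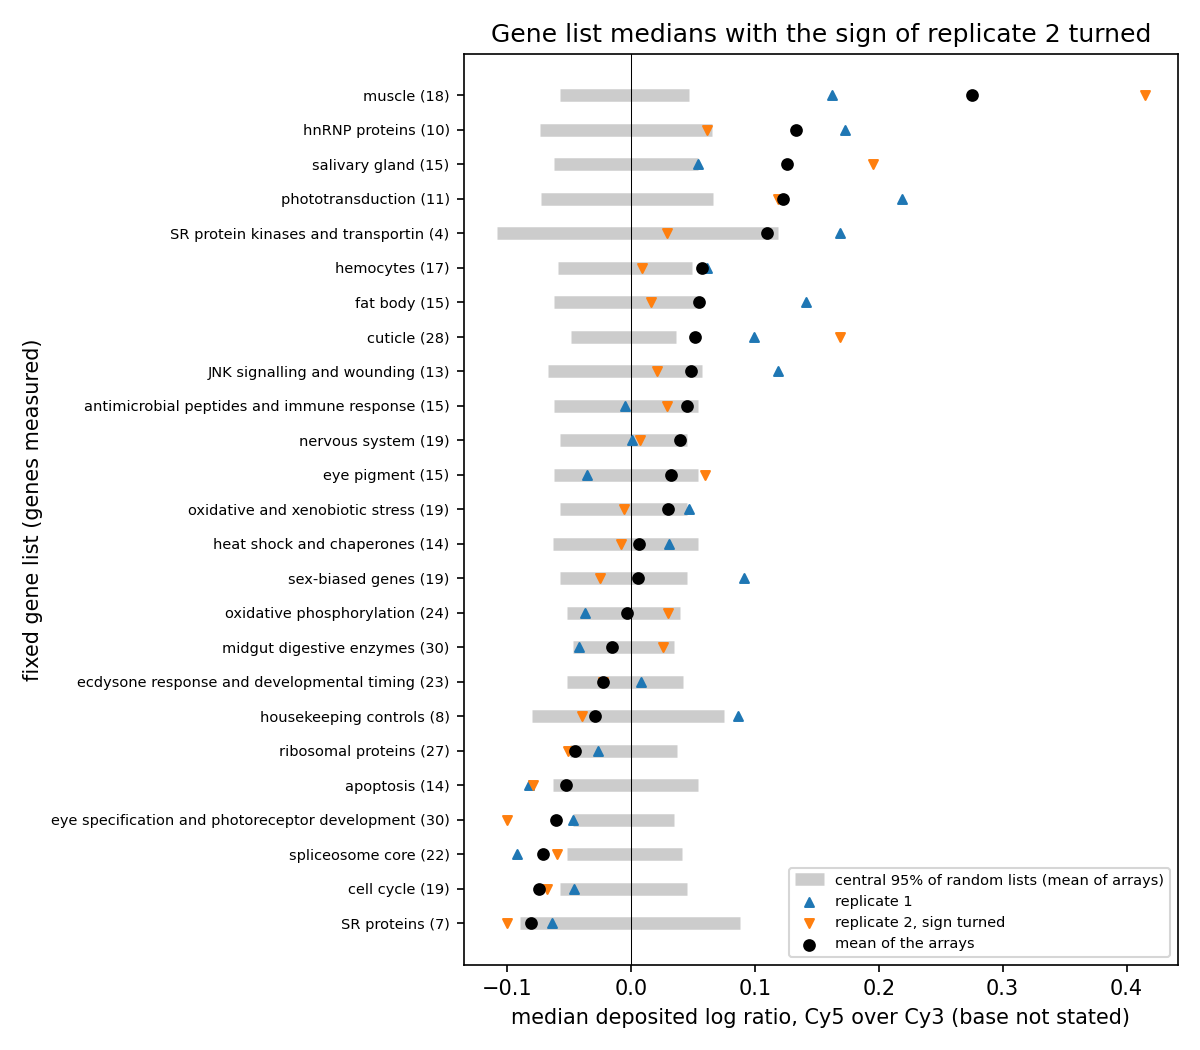
Median deposited log ratio of each fixed gene list in the dye reading (horizontal axis, log base not stated), with replicate 1, replicate 2 with its sign turned, and the mean of the arrays; grey bars are the central 95% of random lists for the mean. The muscle list, at 0.275, lies farthest from its bar.

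Across the tested probes the deposited values of the arrays had a Pearson correlation of 0.00949 (95% interval over print blocks -0.0371 to 0.0526) and a Spearman correlation of 0.0471. Probes are not independent replicates, and no p-value was computed. The median absolute deviation of the mean log ratio was 0.072 in the channel reading and 0.066 in the dye reading, a ratio of 1.09 (95% interval 1.04 to 1.16). With the median of each print block removed the ratio was 0.956 and the Pearson correlation -0.0828. The medians of the 48 print blocks correlated at 0.823 between the arrays. A block offset tied to the dyes would keep its sign in Cy5 over Cy3 values and change it in B52 over control values. Whether these offsets follow the dyes was not tested, so they do not settle the direction.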

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

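All tests in this part were chosen after the values had been seen. Control positions were in no comparison, and 2 of the 40 had medians over 24 spots beyond 0.647 in size on both arrays, the 99th percentile of named probes. The lower had a median of -1.37 on replicate 1 and -0.931 on replicate 2. The higher had 0.701 on replicate 1 and 1.13 on replicate 2. Their RNA is not named in the labels.

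These 2 control positions kept their sign between the arrays, although the dyes of the larval RNAs were exchanged. Of all 40 control positions, 25 had medians of the same sign on both arrays and 15 of opposite sign, with a correlation of 0.586 over 716 spots. Their sign does not settle the direction. Pairs of probes for 1 gene were compared too, since real differences between the RNAs should be shared by both probes. Over the 301 pairs not spaced by an offset that recurs in the layout, the correlation between probes was 0.229 in the dye reading and exceeded that in the channel reading by 0.169 (95% interval 0.00858 to 0.336). Over all 392 pairs the difference was 0.183, and the 86 pairs at that offset gave 0.592 against 0.246. Such a difference would follow if the dye reading holds. It would also follow in the channel reading if 2 probes of 1 gene share a dye bias, which was not tested. Print-block medians were not removed here, the interval comes close to 0 and genes are not independent replicates. The pairs therefore do not settle the direction, and both readings are kept throughout.

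The distance between these 2 control positions was 2.07 on replicate 1 and 2.06 on replicate 2. Another pair of control positions lay 0.88 apart on replicate 1 and 0.875 on replicate 2. Spikes mixed at 10 to 1 and 1 to 10 would lie 2 apart on the log10 scale and 6.64 apart on the log2 scale, and spikes at 3 to 1 and 1 to 3 would lie 0.954 and 3.17 apart. The distances are near those for log10, which may be the log base of the values. Spikes of this kind would also be centred on 0. The midpoints on replicates 1 and 2 were -0.337 and 0.0985 for the wider pair, and -0.411 and -0.146 for the other. The ratios of the control RNAs are not known and log2 ratios can be compressed, so the log base stays open.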

How the results depend on the processing

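The size rule at 0.301, the alternatives in the dye reading, and those with print-block medians removed or control spots kept were chosen after the data were seen. Limma called 0 probes under every alternative run, with 600 to 1018 probes at an unadjusted p under 0.05. With print-block medians removed there were 627 in the channel reading and 919 in the dye reading. The size rule for log10 values gave 190 probes in the channel reading, 345 with control spots kept, 780 at 1.5-fold, 528 for the mean of the arrays and 1123 to 1292 on single arrays. In the dye reading, 203 became 719 at 1.5-fold, 539 for the mean and 1123 to 1292 on single arrays. The planned rule for log2 values gave 0 in both readings, 1 with control spots kept and 20 to 25 on single arrays. At 1.5-fold it gave 9 in the channel reading and 21 in the dye reading, and for the mean 1 and 3. The looser rules and single arrays admit more probes by construction. Lists outside the central range numbered 3 in the channel reading and 10 in the dye reading, and 5 to 9 on single arrays. The dye reading had 9 with extreme probes left out, where cuticle was at 0.007, and 12 without print-block medians, and the channel-reading JNK median was 0.037 without print-block medians, inside the range, while phototransduction moved outside it at 0.0815. The ratio of spreads, 1.09, was 0.917 in the dye reading, 0.956 without print-block medians and 1.01 from standard deviations. The Pearson correlation of 0.00949 became -0.0828 without print-block medians and 0.157 with control spots kept, and Spearman's was 0.0471. The mean of the B52 probes in the channel reading, -0.0468, was 0.0424 without replicate 1 and -0.136 without replicate 2. Of 200 values of list medians under alternatives in each reading, 166 in the channel reading and 163 in the dye reading moved by less than the SD between arrays and were not counted as reversed. For single arrays this follows largely from having 2 arrays. Values counted as reversed, 3 in the channel reading and 4 in the dye reading, turned sign in lists outside the range of random lists, whatever the size of the move. The channel-reading JNK median of 0.0935 was -0.021 without replicate 1 and 0.119 without replicate 2. The channel-reading muscle median of -0.0808 became -0.415 without replicate 1, 0.162 without replicate 2 and 0.275 in the dye reading. From the dye to the channel reading, sign changed for 3 other lists that were outside the range in the dye reading: eye specification (0.0408), the cell cycle (0.033) and the salivary gland (-0.0225). The cause was not tested. Averaging the arrays as 1 technical replicate leaves the means but no test. Signal over background was not analysed here, so no limit from dim spots can be given.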

Other observations

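The gene families and single genes of this part were chosen after their values were seen, as were all tests in it. The 42 odorant receptor genes measured had a median of 0.0968 ± 0.0279 in the channel reading (SD, n = 2 arrays; percentile 100 among random lists), with 24 of them positive on both arrays and 9 negative on both. The median was 0.0668 with print-block medians removed. The 38 ionotropic receptor genes had a median of 0.0592 ± 0.00955 (percentile 99.05), with 21 positive on both arrays and 6 negative on both, or 0.0441 (percentile 96.45) with both arrays scaled to the same spread, inside the central range of random lists. Genes of mitochondrial ribosomal proteins had a median of -0.065 ± 0.0311, below all random lists drawn, with 45 of 69 negative on both arrays and 2 positive on both. Their median was -0.0615 with print-block medians removed. The dye-reading medians of these 3 families were -0.002, 0.002 and -0.0205, the odorant receptor median turning to 0.003 with each array centred and the ionotropic one to -0.00175 with print-block medians removed. Without print-block medians the dye-reading median of mitochondrial ribosomal proteins was -0.029 (percentile 1.95), below the central range of random lists. Gustatory receptors and ppk channel subunits were examined too, with channel-reading medians of 0.0535 (percentile 96.99) and 0.0825 (percentile 98.78). Scaling the arrays to the same spread put gustatory receptors at percentile 98.35, and removing print-block medians put ppk subunits at 87.8. Their dye-reading medians were 0.0207 and -0.046, inside the central range. The receptor, ppk and mitochondrial ribosomal protein families each had deposited medians of the same sign on both arrays. A dye bias would also give that if the values are Cy5 over Cy3, which was not tested. Dimness of their spots could not be judged without intensities.

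The 65 measured cuticle protein genes of the Cpr and Lcp families had a median of 0.0855 ± 0.00566 in the dye reading (SD, n = 2 arrays; percentile 100), with 34 positive on both arrays and 14 negative on both. On the single arrays the medians were 0.095 and 0.103. The median over gene means was 0.098 with print-block medians removed and 0.036 with the 1% most extreme probes left out. In the channel reading it was -0.0285 (percentile 0.825), below the central range of random lists, and -0.003 (percentile 26.07) with those probes left out, or -0.00538 (percentile 19.85) with both arrays scaled to the same spread. Odorant-binding protein genes had a median of 0.061 ± 0.0194 (percentile 99.97) in the dye reading, with 15 positive on both arrays and 3 negative on both, and -0.0178 in the channel reading, where it was 0.000625 with print-block medians removed. Cytochrome P450 genes had medians of 0.0225 (percentile 98.15) in the dye reading and 0.0292 (percentile 91.09) in the channel reading. With the 1% most extreme probes left out, the dye-reading one was 0.0137 (percentile 95.2), inside the central range. Of single genes in the dye reading, ple, the tyrosine hydroxylase gene, had a mean of 0.73 (SE 0.096, limma adjusted p = 0.205). The mean over both probes of Pu, the GTP cyclohydrolase gene, was 0.506 ± 0.038. The mean over 3 probes of Ddc, the dopa decarboxylase gene, was 0.286 ± 0.026.

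A total of 169 genes in the dye reading had a probe past the size rule at 0.301 and 9 had more than 1: CG17549, Ddc, Drat, PCB, Pu, Treh, Zasp52, cnc and sona. For the channel reading 137 genes had such a probe and 0 had more than 1.

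Muscle genes were positive on replicate 1 and negative on replicate 2 in the deposited values. If the values are Cy5 over Cy3, a dye bias would have the same sign on both arrays. A dye bias that grows with transcript abundance could therefore give the pattern only in the channel reading. It should then shift ribosomal protein and oxidative phosphorylation genes the same way. With the sign of replicate 2 turned, their medians were -0.045 and -0.0035, against 0.275 for muscle. With print-block medians removed, that muscle median was 0.274. In the dye reading, a difference in stage or tissue make-up between the larvae behind each RNA may account for the pattern. An effect of B52 could too, although the mean of its own probes was -0.0892 in that reading. Probe 13309 at -0.41 weighed most on that mean, and the other B52 probes lay between -0.0935 and 0.101. In the channel reading, an effect of B52, or a difference in stage or tissue shared by both arrays, would have the same sign on both. The dye-reading salivary gland median of 0.126 was above random lists, though not on replicate 1 alone (percentile 87.77). Those of cuticle (0.0513), hemocytes (0.0575) and fat body (0.0545) were above too. Cuticle was not with the 1% most extreme probes left out, and the other 2 were not on replicate 2 alone. The medians of the ecdysone response and developmental timing (-0.0225), midgut (-0.0157) and nervous system (0.0395) were inside the range. Within the dye reading, stage or tissue make-up and B52 cannot be told apart, since no other pair of RNAs is named. A dye bias of the muscle probes themselves, possible in the channel reading, was not tested.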
